A study of Homo sapiens with 24 samples.

How the data were processed

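Small RNA was sequenced from 24 tumours of C4-2B, a castration-resistant human prostate cancer cell line, grown under the skin of nude mice. Per the labels' protocols, treatment began once tumours could be seen, and tumours were taken once they reached 1000 mm3 or when 21 days of dosing had passed, then dissociated mechanically and with collagenase before RNA isolation on miRNeasy columns. Libraries were made with the QIAseq miRNA kit, which tags each captured molecule with a unique molecular index (UMI), so that amplified copies are counted once. Per the submitters' processing notes, bcl2fastq 2.19 and DESeq2 (version not given) were used and the build was GRCh37 (hg19). The aligner and the handling of mouse reads are not given in the sources used here. Many conserved miRNAs have the same mature sequence in mouse. Lists of blood, leukocyte, endothelial, fibroblast and muscle miRNAs may therefore measure mouse host cells, and this was not tested.

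The values used are the authors' own comparisons of each group with vehicle, and no values per tumour were used. For this reason the count test planned before the data were examined was replaced by its stated fallback, in which the authors' fold and p are taken as deposited. The fold regulation is a signed score: per the file headers it equals the fold change for a miRNA above vehicle and the negative inverse of the fold change for one below, and it is deposited with 2 decimals. The p-value is deposited unadjusted, and per the file headers it was returned by the normalization package and needs at least 3 samples in each group, so the untreated table has none. A second set of tables, prepared by the authors for pathway software, gives the same comparison as a ratio (fold change) with its p-value. Comments in the deposited tables mark miRNAs that average under 10 UMIs in one of the compared groups, under 10 in both, or zero in both. Whether the authors' folds were shrunken toward 1 is not given in the sources used here. The depth of each library is unknown, so the comments are the only guide to the counts behind a fold.

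Each table lists 3093 RNAs, of which 2554 are miRNAs and 539 are piRNAs. A log2 fold was computed from each fold regulation. The deposited p-values were adjusted by the Benjamini-Hochberg method over the miRNAs with a p in that table, and a miRNA was called at an adjusted p below 0.05. The standard error implied by a fold and its p was the size of the log2 fold over the normal deviate of the two-sided p, which assumes a Wald test. For folds under 1.1, where rounding sets this ratio, the median of miRNAs with the same comment was used. The error serves only for centred or corrected recounts and for differences between arms.

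The miRNAs named were fixed by a rule written before the data were examined. In each comparison they are the 10 called miRNAs each way with the largest fold, among those in the upper part of the tested miRNAs by p, and up to 4 called members of each of 16 fixed lists by smallest p. Where none was called, they are the 10 with the smallest unadjusted p. For a combination against its part they are the 5 largest differences each way among miRNAs called in either table, and miR-21-5p, miR-34a-5p, miR-221-3p, miR-222-3p, miR-375, miR-148a-3p, miR-32-5p and miR-451a are given throughout. Other list members given as examples were chosen after their values were seen. Of each list, the members past a threshold were counted, and the median log2 fold was placed among 10000 random lists of the same size drawn from all miRNAs with counts, as a two-sided p adjusted over the 16 lists. The smallest p this can give is 0.0002 before adjustment. Random lists take members as independent, so a list of co-transcribed miRNAs gives a p that is too small.

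All comparisons share the 3 vehicle libraries. Overlaps and correlations between arms are therefore given beside 100 simulations of unchanged groups against a shared vehicle and beside the overlap of independent lists. The simulations take tumours of all groups to vary equally and miRNAs as independent. Where this does not hold, a simulated value can be too high or too low, so a gap from it does not by itself show a drug effect. Hairpin GC content came from the miRNA transcripts of GENCODE 29, in which 2548 of the 2554 miRNAs were matched by name. The deposited tables carry no coordinates and name another build than this annotation, so no positions are given. Alternatives tried were other p thresholds, a minimum fold, adjustment with the piRNAs, the pathway-software tables, centring of the folds and, chosen after seeing the data, a filter on the low-count comments (for calls, and for list members together with random lists), GC corrections over 10 bins of hairpin GC content and tests of differences between arms. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated tables built on the implied errors of each arm with a set of changed miRNAs. Of miRNAs changed by 2 on the log2 scale, 97.0% were recovered for MMF, 100% for abiraterone, 96.9% for ARN-509, 88.9% for MMF + ARN-509 and 56.0% for the combination with abiraterone. At a change of 1 these shares were 37.9%, 60.8%, 34.8%, 11.7% and 8.20%. In the same order, 1.09%, 8.33%, 3.23%, 4.05% and 5.77% of the calls were false, in 1 simulated table per arm. The noise was drawn from the implied errors, so this does not test whether those errors are right.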

Results

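The miRNA content of C4-2B xenografts was compared between 7 groups. Mycophenolate mofetil (MMF), a prodrug whose active form blocks IMPDH in guanine nucleotide synthesis, was given at 100 mg/kg to 4 tumours. Abiraterone, an inhibitor of androgen synthesis, was given at 0.5 mmol/kg per day to 4, and ARN-509 (apalutamide), an antagonist of the androgen receptor, at 30 mg/kg to 4. MMF with ARN-509 was given to 3 tumours, and MMF with abiraterone and 20 mg/kg prednisolone phosphate, the 3-drug combination below, to 4. The controls were 3 vehicle tumours, which received the oil carrier used for abiraterone, and 2 untreated tumours. The label of the abiraterone arm breaks off, so whether it also received prednisolone is not known. MMF alone and ARN-509 alone had other carriers and another route than vehicle, so their comparisons also contain that difference. The labels do not say that each tumour came from its own mouse, so p-values measure the spread between these samples. All folds and p-values below are those of the authors' deposited tables against vehicle, and adjusted p-values are Benjamini-Hochberg values computed from them. How many tumours of a group shared a direction cannot be read from these tables.

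The first question was what nucleotide synthesis inhibition does alone. With MMF, 4 miRNAs rose and 3 fell among the 2496 with a p. In the authors' deposited table, miR-2392 was 3.38-fold higher (adjusted p = 0.00669), miR-548as-3p 3.21-fold, miR-548i 3.10-fold and miR-4764-3p 3.04-fold higher. The authors' deposited table has miR-1471 2.95-fold lower (adjusted p = 0.000555), miR-4468 2.50-fold lower and miR-6819-3p 2.36-fold lower. All 7 averaged at least 10 UMIs in both groups. The erythroid miRNAs, abundant in red blood cells and their precursors, formed the 1 list of 16 whose median stood apart. All 5 members were below vehicle, with a median log2 fold of -1.21 (adjusted p = 0.0032 against random lists). None was called over all miRNAs and 3 were lower when adjusted over the list alone. By the authors' deposited table these were miR-144-5p, 3.05-fold lower, miR-486-5p, 2.39-fold lower, and miR-486-3p, 2.31-fold lower. The other 15 lists had adjusted p-values of at least 0.738 and medians between -0.29 and 0.30. They comprised androgen-induced, androgen-repressed, p53 target, miR-17/92, let-7, miR-29, epithelial and prostate luminal, hypoxia, endothelial, leukocyte, fibroblast and smooth muscle, skeletal and cardiac muscle, liver, neuronal and neuroendocrine, and 14q32 cluster miRNAs. Single members passed over the list alone for miR-210-5p (hypoxia), 1.80-fold higher, and miR-137 (neuronal), 2.34-fold higher, in the authors' deposited table. The hypoxia list has 2 members, and the other, miR-210-3p, lay below vehicle with a log2 fold of -0.25. Of the miRNAs given throughout, the authors' deposited table has miR-21-5p 1.32-fold, miR-32-5p 1.46-fold, miR-375 1.09-fold, miR-34a-5p 1.08-fold, miR-222-3p 1.07-fold and miR-221-3p 1.02-fold above vehicle, miR-148a-3p at 1.00 and miR-451a 1.63-fold below, with no call among them. Log2 folds fell with hairpin GC content across miRNAs (Spearman rho = -0.33), and a correction for it, which also centres the folds, ended 5 calls with little change of most folds. From the authors' deposited table, log2 folds went from 1.63 to 1.49 for miR-548i, 1.60 to 1.58 for miR-4764-3p, -1.32 to -1.28 for miR-4468 and -1.24 to -0.98 for miR-6819-3p, and Benjamini-Hochberg adjusted p-values to between 0.0534 and 0.105. The fifth, miR-548as-3p, had a log2 fold of 1.68 before and an adjusted p of 0.0549 after. Correlations across miRNAs, here and below, are not over independent replicates.

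With abiraterone, miR-561-5p fell, being 2.76-fold lower in the authors' deposited table (adjusted p = 0.0302). It was the 1 call among 2532 miRNAs, and centring on the median of all tested miRNAs ended it (adjusted p = 0.0648), as did the GC correction (0.0647), with a log2 fold of -1.46 before and -1.41 after either. With the overall median kept, the GC correction left 1 call. Fibroblast and smooth muscle miRNAs stood apart from random lists, with all 10 members above vehicle and a median log2 fold of 0.84 (adjusted p = 0.0032). None was called over all miRNAs, and 6 were higher when adjusted over the list alone. In the authors' deposited table miR-199b-5p was 2.25-fold, miR-199b-3p 2.16-fold, miR-199a-5p 2.02-fold, miR-145-5p 1.86-fold and miR-214-3p 1.73-fold above vehicle, and miR-199a-3p had a log2 fold of 1.13. These miRNAs are abundant in mesenchymal cells, and miR-199a-3p and miR-199b-3p share a mature sequence. Leukocyte miRNAs had a median of 0.40 (adjusted p = 0.0272), with 0 of 8 members past even an unadjusted p of 0.05. In the 14q32 cluster, an imprinted locus of many miRNAs, 4 of 28 members were higher when adjusted over the list alone. The authors' deposited table has miR-379-5p at 2.17-fold, miR-411-5p at 2.16-fold, miR-382-5p at 1.94-fold and miR-381-3p at 1.86-fold above vehicle, while the list median of 0.14 did not stand apart (adjusted p = 0.0872). Single members passed over the list alone for miR-100-5p of the androgen-repressed list, 2.35-fold higher, and miR-34c-5p of the p53 list, 2.20-fold higher, in the authors' deposited table. Erythroid miRNAs lay near vehicle, with a median of 0.04. The authors' deposited table has miR-21-5p 1.61-fold, miR-375 1.49-fold, miR-221-3p 1.17-fold, miR-222-3p 1.15-fold and miR-451a 1.05-fold above vehicle, miR-34a-5p at 1.00, and miR-32-5p 1.23-fold and miR-148a-3p 1.04-fold below, none of them called.

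With ARN-509, miR-486-5p fell, being 5.20-fold lower in the authors' deposited table (adjusted p = 0.00080). The erythroid list as a whole was below vehicle in 5 of 5 members, with a median log2 fold of -1.27 (adjusted p = 0.0016), and 3 members were lower over the list alone. In the skeletal and cardiac muscle list the median was -0.86 (adjusted p = 0.0016). This rests on 4 members that have no p in the authors' deposited table, namely miR-1-3p, 2.42-fold lower, miR-206, 2.25-fold lower, miR-133b, 2.13-fold lower, and miR-133a-3p, 1.82-fold lower. Another member, miR-208b-3p, was 1.81-fold higher in the authors' deposited table and passed over the list alone, in which only 3 of 7 members had a p. Androgen-induced miRNAs lay mostly above vehicle, 9 of 12, with a median of 0.34 that did not stand apart (adjusted p = 0.0853), although it did against random lists matched on GC content (adjusted p = 0.0464), as did the epithelial and prostate luminal list (adjusted p = 0.0427), which shares members with it. The androgen-induced members with the smallest p in the authors' deposited table were miR-32-5p, 2.10-fold higher, miR-19a-3p, 2.13-fold higher, and miR-135a-5p, 1.59-fold higher, and 0 of the 12 passed over the list alone. Over the list alone miR-134-5p and miR-433-3p of 14q32 were lower, by 2.03-fold and 1.94-fold in the authors' deposited table, and miR-889-3p was 2.24-fold higher. The same holds for miR-150-5p, 2.00-fold lower, miR-223-5p, 2.54-fold higher, and miR-34b-5p, 1.91-fold higher, in the authors' deposited table. The authors' deposited table has miR-148a-3p 1.46-fold, miR-21-5p 1.27-fold and miR-375 1.15-fold above vehicle, and miR-451a 1.75-fold, miR-221-3p 1.27-fold, miR-222-3p 1.25-fold and miR-34a-5p 1.20-fold below, none of them called. The count of 1 depends on centring, since 34 miRNAs were higher and 3 lower once folds were centred on the median of all tested miRNAs, a shift of -0.10. GC content and log2 fold were related more closely than with MMF (rho = -0.45).

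Abiraterone and ARN-509 both act on the androgen axis and were set side by side. Their log2 folds differed most, among the called miRNAs, for miR-486-5p, by 2.42, and for miR-561-5p, by -2.38 (abiraterone minus ARN-509), the latter being 1.89-fold above vehicle with ARN-509 in the authors' deposited table. Both differences passed a test that counts the shared vehicle variance once per arm and so overstates the error (adjusted p = 0.0186 and 0.0157). Across 2509 miRNAs the log2 folds had a correlation of 0.28, against 0.56 simulated for unchanged groups with a shared vehicle, and a covariance of 0.0439 against 0.0648. At an unadjusted p below 0.05, 28 miRNAs were above vehicle with both drugs and 12 below, against 14.4 per direction simulated and 8.20 and 2.23 for independent lists.

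With MMF and ARN-509 together, 0 of 2499 miRNAs were called from the p-values that the authors obtained with DESeq2, while 179 had an unadjusted p below 0.05. The smallest p in the authors' deposited table was that of miR-4665-5p, 2.82-fold lower (adjusted p = 0.206). None of the next 9 passed. In the authors' deposited table, miR-6821-5p was 2.99-fold, miR-939-5p 2.74-fold, miR-3183 2.71-fold, miR-4673 2.63-fold, miR-1471 2.52-fold and miR-134-5p 2.25-fold lower, and miR-548q 2.76-fold, miR-3973 2.64-fold and miR-376c-5p 2.51-fold higher. Erythroid miRNAs were below vehicle in 5 of 5 members, with a median log2 fold of -1.15 (adjusted p = 0.0016), and 4 passed over the list alone. Leukocyte miRNAs had a median of -0.79 (adjusted p = 0.0016). Over the list alone 4 were lower, given in the authors' deposited table as miR-142-3p, 2.31-fold, miR-142-5p, 2.24-fold, miR-155-5p, 2.08-fold, and miR-150-5p, 1.88-fold, and miR-223-5p was higher by a log2 fold of 1.13. In the androgen-induced list 1 of 12, miR-135a-5p, was higher over the list alone, with a log2 fold of 1.13 in the authors' deposited table, and the list median of 0.01 did not stand apart. The muscle list had a median of -0.87 (adjusted p = 0.00213), and the same 4 members as with ARN-509 had no p. The authors' deposited table has miR-32-5p 1.42-fold, miR-375 1.17-fold and miR-148a-3p 1.15-fold above vehicle, and miR-451a 2.32-fold, miR-221-3p 1.34-fold, miR-222-3p 1.33-fold, miR-34a-5p 1.22-fold and miR-21-5p 1.01-fold below.

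This combination was set against its parts at the miRNAs called with either drug alone. Picking miRNAs by their call in a single-drug table makes smaller folds in another table likely by itself. In a test of the difference built on the errors implied by the authors' DESeq2 p-values, 0 miRNAs differed from ARN-509 (5 at an unadjusted p below 0.05) and 0 from MMF (21). For miR-486-5p the authors' deposited table has 2.22-fold lower with the combination and 5.20-fold lower with ARN-509. The difference of log2 fold from MMF was -0.82 for miR-2392, -0.74 for miR-548i, -0.65 for miR-548as-3p and -0.43 for miR-4764-3p, from the authors' deposited tables. It was higher by 0.82 for miR-4468, by 0.23 for miR-1471 and by 0.11 for miR-6819-3p in the authors' deposited tables. The log2 folds of the combination had a correlation of 0.80 with ARN-509 (simulated 0.53; covariance 0.179, simulated 0.0882) and of 0.68 with MMF (simulated 0.53; covariance 0.138, simulated 0.0850).

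**Figure D1:**
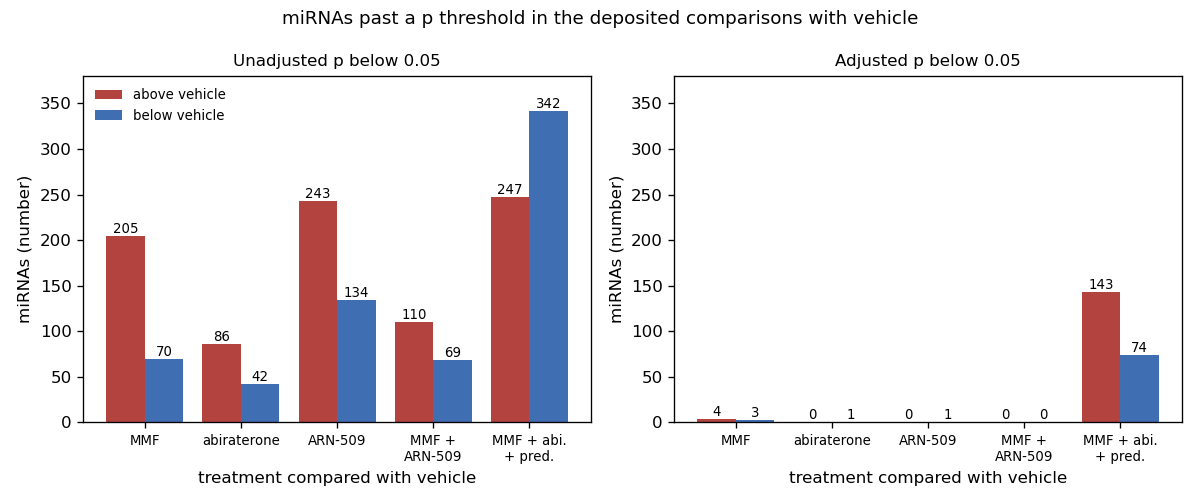
Number of miRNAs past an unadjusted (left) or adjusted (right) p of 0.05 in each treatment against vehicle, with bars for those above and below vehicle. The 3-drug combination had 143 and 74 adjusted calls, and the other treatments between 0 and 7 in all.

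With MMF, abiraterone and prednisolone, 143 miRNAs rose and 74 fell among 2502, while at an unadjusted p below 0.05 more were below vehicle (342) than above (247). The largest rises in the authors' deposited table were those of miR-4295, 6.73-fold, miR-8054, 6.59-fold, miR-3620-3p, 6.16-fold, and miR-2392, 6.14-fold. In the same authors' deposited table miR-7114-5p was 5.94-fold, miR-4761-3p and miR-4764-3p 5.76-fold, miR-4485-3p and miR-6823-5p 5.61-fold and miR-561-3p 5.53-fold higher. The largest falls in the authors' deposited table were those of miR-6511a-5p, 14.99-fold, miR-6814-3p, 14.26-fold, miR-6843-3p and miR-939-5p, 9.32-fold, miR-1227-5p, 9.22-fold, and miR-6800-3p, 9.14-fold. They were followed in the authors' deposited table by miR-6886-3p, 8.99-fold, miR-525-5p, 8.77-fold, miR-5692b, 8.44-fold, and miR-4776-3p, 8.09-fold lower. These 10 all averaged under 10 UMIs in one of the groups, as did 53 of the 74 that fell, whereas all 143 that rose averaged at least 10 in both. In this comparison 1155 miRNAs had that comment, against 96 to 335 in the other treatments and 889 in untreated tumours.

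Erythroid miRNAs were again below vehicle in 5 of 5 members, with 2 called and 4 lower over the list alone. By the authors' deposited table miR-486-5p was 4.79-fold lower (adjusted p = 0.0107) and miR-144-5p 4.78-fold lower (adjusted p = 0.0195). The list median of -1.50 did not stand apart from all miRNAs with counts (adjusted p = 0.0992), whose own median was -0.44. With members and random lists both limited to miRNAs averaging at least 10 UMIs, it did (adjusted p = 0.0032). The same held for the muscle list, with a median of -1.34 over 5 such members, but 3 of its 7 members had no p. The 14q32 list did not stand apart in either of these ways, with a median of -0.74 over 28 members (adjusted p = 0.197) and -0.33 over the 16 averaging at least 10 UMIs (adjusted p = 0.230). The limit to 10 UMIs decides little for a low list. Of the 1155 miRNAs averaging under 10 UMIs in one of the groups, 1112 lay below vehicle. All 5 erythroid members averaged at least 10 UMIs, so for them the limit changed only the random lists. In 14q32, miR-889-3p rose 3.39-fold and miR-493-3p, miR-433-3p and miR-134-5p fell by 5.21-fold, 2.77-fold and 2.55-fold in the authors' deposited table. Fibroblast miR-199b-5p and miR-199a-5p rose 2.58-fold and 1.86-fold, and miR-223-5p, of myeloid cells, rose 4.41-fold (adjusted p = 7.7e-05), in the authors' deposited table. The other 12 lists had no call, and over the list alone the liver miRNA miR-122-5p was 2.75-fold higher in the authors' deposited table. The authors' deposited table has miR-148a-3p 1.77-fold, miR-32-5p 1.72-fold, miR-34a-5p 1.41-fold, miR-375 1.20-fold, miR-221-3p 1.15-fold and miR-222-3p 1.09-fold above vehicle and miR-451a 2.64-fold below, none of them called, and miR-21-5p 2.79-fold above with no p. The split of calls depended on scaling: 271 were higher and 20 lower with folds centred on the median of all tested miRNAs, and 149 and 25 among miRNAs averaging at least 10 UMIs. Centring on all tested miRNAs ended 4 named falls, whose log2 folds went from -2.26 to -1.81 for miR-144-5p, -1.47 to -1.03 for miR-433-3p, -2.38 to -1.94 for miR-493-3p and -1.35 to -0.91 for miR-134-5p, from the authors' deposited table. Centring on those averaging at least 10 UMIs ended the rises of miR-199b-5p and miR-199a-5p. The log2 folds of the latter pair went from 1.37 to 1.28 and from 0.90 to 0.81. The GC correction, which also centres the folds, left 13 of the 74 falls past the threshold and ended 7 of those named here. From the authors' deposited table, log2 folds went from -3.20 to -2.36 for miR-1227-5p, -3.19 to -2.34 for miR-6800-3p, -2.26 to -1.50 for miR-486-5p, -2.26 to -1.82 for miR-144-5p, -1.47 to -0.94 for miR-433-3p, -2.38 to -1.86 for miR-493-3p and -1.35 to -0.75 for miR-134-5p.

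Against abiraterone, the 3-drug combination had the largest positive differences of log2 fold at miR-518c-3p, 2.44, miR-548am-3p, 2.32, miR-559, 2.22, miR-4798-5p, 2.20, and miR-766-5p, 2.17, from the authors' deposited tables. The largest negative ones from the authors' deposited tables were at miR-6814-3p, -3.66, miR-6511a-5p, -3.30, miR-1227-5p, -3.19, miR-6861-5p, -3.07, and miR-6886-3p, -2.98. Against MMF they were positive at miR-4295, 1.69, miR-3620-3p, 1.62, miR-499b-3p, 1.59, miR-3943, 1.49, and miR-518c-3p, 1.48, from the authors' deposited tables. They were negative at miR-6814-3p, -3.55, miR-6843-3p, -3.10, miR-6511a-5p, -3.09, miR-4526, -2.92, and miR-5692b, -2.90, from the authors' deposited tables. The negative differences are at miRNAs with under 10 UMIs in one of the groups. Of the 3 rises and 3 falls with MMF that had a p in both tables, 3 and 2 were called in the same direction with the combination, against 0.157 and 0.0902 for independent lists. At an unadjusted p below 0.05, 140 were above vehicle in both tables and 34 below, against 13.9 per direction simulated for unchanged groups with a shared vehicle and 18.2 and 9.58 for independent lists. The correlation of log2 folds was 0.73 with MMF (simulated 0.55; covariance 0.308, simulated 0.125). With abiraterone it was 0.47, below the simulated 0.55, while the covariance of 0.144 was above the simulated 0.108.

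Untreated tumours were compared with vehicle without a p. Androgen-induced miRNAs had a median log2 fold of 0.54 and epithelial and prostate luminal miRNAs one of 0.54, both apart from random lists (adjusted p = 0.0288), though not with members and random lists limited to miRNAs averaging at least 10 UMIs (adjusted p = 0.221). Both lists share members such as miR-148a-3p, so they are not separate results. These p-values are over miRNAs and do not measure the spread between tumours. The authors' deposited table has miR-21-5p 2.00-fold, miR-148a-3p 1.77-fold, miR-375 1.64-fold, miR-221-3p 1.32-fold, miR-222-3p 1.18-fold, miR-32-5p 1.16-fold and miR-34a-5p 1.08-fold above vehicle and miR-451a 1.18-fold below. Erythroid miRNAs were below vehicle in 5 of 5 members, with a median of -0.40, which did not stand apart (adjusted p = 0.538).

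**Figure D2:**
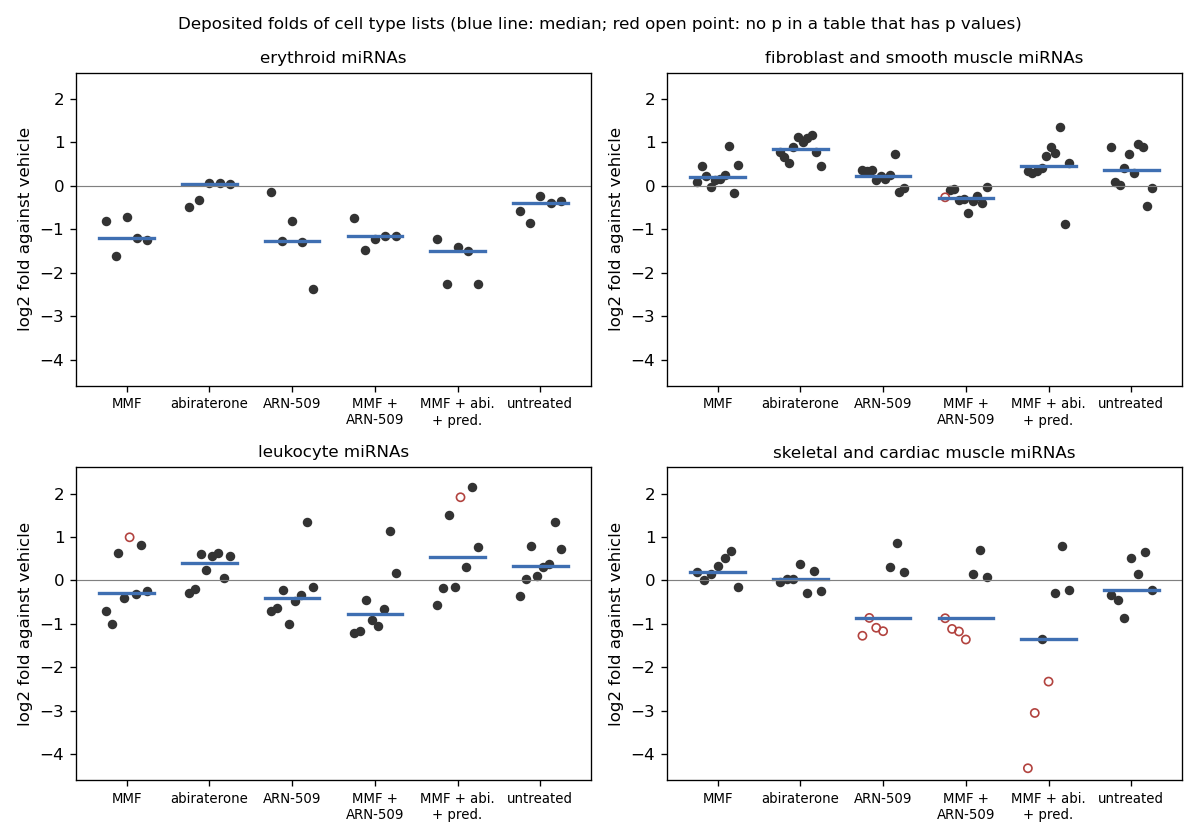
Log2 fold against vehicle (vertical axis) of each member of 4 cell type lists in each comparison (horizontal axis). Points are members, the blue line is the list median and red open points have no p in a table that gives p-values; erythroid medians lie between -1.15 and -1.50 in 4 treatments and at 0.04 with abiraterone.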

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

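The tests by GC correction without the overall median kept were set out after the GC trend had been seen but before their own results, and the tests of differences between arms and from abiraterone, low counts, untreated tumours, blood, missing p-values and the GC correction with the overall median kept were chosen after the result was seen.

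The folds of 2 miRNAs differed between abiraterone and ARN-509, and those of 17 between abiraterone and the 3-drug combination, in a test of the difference itself. Of the 17, 15 were higher with the combination, among them miR-559, miR-518c-3p and miR-223-5p. This direction depends on the error used: with the shared vehicle variance taken out 493 differed, and 305 of them were higher with abiraterone. The other pairs of treatments gave 0 in this test, built on the authors' DESeq2 p-values with an error that is an upper bound (5 to 128 at an unadjusted p below 0.05). With the shared vehicle variance taken out, which assumes that tumours vary equally in all groups, they gave 110 (MMF and the 3-drug combination), 101 (ARN-509 and the 3-drug combination), 60 (MMF and abiraterone), 30 (MMF with ARN-509 and the 3-drug combination), 18 (abiraterone and MMF with ARN-509) and 0 for the rest. Among miRNAs averaging at least 10 UMIs, the median implied error was 0.469 for the 3-drug combination and 0.310 for abiraterone, each with 4 tumours. Unequal errors at equal group sizes go against that assumption, so counts with the 3-drug combination can be too high.

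The piRNAs, outside the main comparisons, also differed from vehicle, with adjustment over the piRNAs alone. There were 50 past the threshold with the 3-drug combination (24 higher and 26 lower, 27 of them averaging at least 10 UMIs in both groups), 14 with ARN-509, 5 with MMF and ARN-509 together and 1 with abiraterone, and 0 with MMF (44 at an unadjusted p below 0.05, from the authors' DESeq2 values). In the authors' deposited table hsa_piR_017033 was 5.60-fold lower with the 3-drug combination and 2.91-fold lower with MMF and ARN-509.

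The many calls of the 3-drug combination were weighed first. The low-count comments decide nothing for low counts in the combination libraries, because the direction of a change largely sets the comment. All 143 rises averaged at least 10 UMIs in both groups, and 53 of the 74 falls had the comment, which a true loss gives too. After the GC correction 142 of the rises remained past the threshold. This decides little, because that correction also centres the folds and moved their median log2 fold up from 1.62 to 2.03. With the overall median kept, 116 remained and the median was 1.59. This argues against a trend with hairpin GC content as the whole source of the rises. Of the falls 13 remained, with the median log2 fold going from -2.42 (quartiles -2.77 and -1.90) to -1.72 (-2.15 and -1.25), but that correction also centres the folds. The rule set before this result took GC content as a source if most calls ended, and for the falls it was met. With the overall median kept, a setting chosen after that, 40 of the 74 remained, a narrow majority. Their median went only to -2.17 (-2.59 and -1.69), which argues against the GC trend as the whole source of the falls. A part of it in the calls that ended stays open. Vehicle cancels in a difference between arms, so levels in the vehicle libraries alone are argued against for the 15 rises and 2 falls that differed from abiraterone in the same direction. Their median log2 folds in untreated tumours were 0.78 and -0.71, so a part from vehicle levels stays open. The difference may also lie in the abiraterone arm. There the 143 rises had a median of 0.39, against 0.96 with MMF, 0.94 with ARN-509 and 0.90 with both. For the 74 falls these medians were -0.24, -0.46, -0.64 and -0.61. With the shared vehicle variance taken out, under the same assumption of equal variance, the rises and falls that differed from abiraterone were 122 and 72. The implied errors go against that assumption (median 0.469 with the combination, 0.310 with abiraterone), so these 2 counts can be too high. For the other 128 rises and 72 falls by the first count, vehicle levels cannot be told apart from other sources. Their median log2 folds were 1.12 and -0.79 in untreated tumours, which had no drug, but 0.43 (quartiles 0.19 and 0.66) and -0.24 (-0.37 and -0.07) with abiraterone, against 1.61 and -2.42 with the combination. The sets were picked by their fold in the combination against the same vehicle libraries, which enlarges the last pair and builds part of the shared direction in. An effect of the drugs stays open for all of them.

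The second pattern was the lower erythroid miRNAs. GC content is argued against as the whole source with ARN-509, where the list median was still -0.94 after the correction. Against random lists matched on GC content, the list stood apart with MMF (adjusted p = 0.0032), ARN-509 (0.0016) and both (0.00107). With the 3-drug combination it did not (adjusted p = 0.0763), so a part of GC content stays open there. Vehicle tumours rich in blood, as the only source, are argued against for miR-486-5p, since vehicle cancels in its difference of 2.42 between abiraterone and ARN-509 (Benjamini-Hochberg adjusted p = 0.0186). For the list as a whole this cannot be told apart from less blood RNA in the drug-treated tumours: the mean over the 5 members was higher by 1.06 with abiraterone than with ARN-509, which is 1.82 times its error with fully correlated members. That error also counts the shared vehicle variance once per arm, so it is an upper bound, and the outcome depends on this choice. All 20 of 20 values (5 members in 4 arms) lay below vehicle, miR-451a among them, but this restates the pattern, and all 5 members also lay below vehicle in untreated tumours (median -0.40). The leukocyte list, of cells found both in blood and in tissue, did not move with it in every arm: its median was -0.29 with MMF, -0.41 with ARN-509 (7 of 8 below vehicle) and -0.79 with both, but 0.53 with the 3-drug combination. Abiraterone shares its oil carrier with vehicle, and the label of the 3-drug combination also gives abiraterone in vehicle. All 5 members were still below vehicle with that combination (median -1.50, 4 lower over the list alone). This argues only against a lack of the oil carrier as the whole source of the fall in that arm. MMF alone had another carrier and route than vehicle, and MMF was part of that combination too. An effect of the drugs, or of carrier and route, therefore stays open and untested in all 4 arms.

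The third was the muscle miRNAs without a p. With ARN-509, 4 of 7 lacked one, against 0.983% of all miRNAs with counts (one-sided exact hypergeometric p = 2.49e-07, too small since members of a co-expressed list are not independent). This test restates the pattern and decides nothing about its source. With MMF and ARN-509 4 of 7 lacked a p, with the 3-drug combination 3 of 7, and with MMF or abiraterone alone 0 of 7. One or a few libraries rich in muscle RNA may be the source, which stays open, as the tables used here hold no values per library. No biological explanation was tested.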

How the results depend on the processing

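The filter on low-count comments, centring on the miRNAs averaging at least 10 UMIs, the GC corrections, the limits on list members and random lists and the tests between arms were chosen after seeing the data. No paired analysis was possible because the deposited comparisons hold no values per tumour, and for the same reason other count tests and normalizations, leaving out single tumours, pseudocounts, camera, split controls and other splits of the samples were not run. Filters on mean level were not run either, since no level is given, nor was the pathway-software table of MMF, which is a copy of its fold table.

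At an unadjusted p below 0.05 there were 275 miRNAs for MMF (7 called), 128 for abiraterone (1), 377 for ARN-509 (1), 179 for MMF and ARN-509 (0) and 589 for the 3-drug combination (217). An adjusted p below 0.10 gave 32 for MMF and 59 for ARN-509. Below 0.01 there were 2 for MMF, 0 for abiraterone and 112 for the 3-drug combination. Adjustment with the piRNAs gave 8 for ARN-509. Centring on all tested miRNAs gave 0 for abiraterone and 37 for ARN-509. For ARN-509, the low-count filter and centring on miRNAs averaging at least 10 UMIs each gave 4. The GC correction gave 3 for MMF, 0 for abiraterone and 8 for ARN-509, and with the overall median kept 2 for MMF. Unless the setting itself removes miRNAs or moves a threshold, the cause was not tested. All other counts stayed within 1.5 times, and MMF with ARN-509 had 0 under each adjusted setting. Centring on miRNAs averaging at least 10 UMIs split the 3-drug calls into 126 higher and 87 lower.

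With the shared vehicle variance taken out, the count differing between abiraterone and the 3-drug combination went from 17 to 493, and between abiraterone and ARN-509 from 2 to 168, so these counts depend on how that variance is assigned, here with tumours of all groups taken to vary equally. The implied errors go against this for the 3-drug combination, so the 493 can be too high. The direction turned as well: 15 of the 17 were higher with the combination, but 305 of the 493 were higher with abiraterone. With list members and random lists limited to miRNAs averaging at least 10 UMIs, 92 of the 96 list results kept their side of the threshold, 2 came to stand apart (erythroid and muscle, 3-drug combination) and 2 no longer did (androgen-induced and epithelial, untreated). With only the random lists limited in this way, 3 came to stand apart, with 14q32 in the 3-drug combination added (median -0.74, adjusted p = 0.00107), and the same 2 no longer did. That setting takes fallen miRNAs out of the random lists but not out of the list, so a low list is favoured by its construction. For the erythroid list in the 3-drug combination the other setting does the same, since all 5 members averaged at least 10 UMIs. Of the 87 results for named miRNAs in each setting, 13 lost their call with the GC correction, 5 with centring on all tested miRNAs and 2 with centring on those averaging at least 10 UMIs, and 2 gained one with each of the first pair. None reversed. The depth of the libraries is unknown, so what it limits cannot be given beyond the low-count comments.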

Other observations

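Several miRNAs that rose with the 3-drug combination lay above vehicle in every table. In the authors' deposited tables miR-889-3p was 2.25-fold higher with MMF (no p), 2.24-fold with ARN-509, 2.21-fold with MMF and ARN-509, 3.39-fold with the 3-drug combination and 2.99-fold in untreated tumours, but 1.15-fold with abiraterone. For miR-223-5p the authors' deposited tables give 1.75-fold with MMF, 2.54-fold with ARN-509, 4.41-fold with the 3-drug combination, 2.55-fold in untreated tumours and 1.04-fold with abiraterone. The other strand of its hairpin, miR-223-3p, was 1.23-fold above vehicle with the 3-drug combination in the authors' deposited table (Benjamini-Hochberg adjusted p = 0.627).

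Of the 143 that rose, 143 were above vehicle with MMF, 143 with ARN-509, 141 with MMF and ARN-509, 137 in untreated tumours and 120 with abiraterone. All 6 tables share the vehicle libraries, so a shared sign is partly built in. These miRNAs were chosen after their values were seen.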
